A study of Physcomitrium patens with 15 samples.

How the data were processed

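RNA of gametophores of Physcomitrium patens, grown on BCD medium per the labels, was sequenced in 15 libraries, 3 in each of 5 states of hydration. The series design calls the 3 libraries of a state biological replicates. The deposited files of each library give counts, headed as unique reads per transcript, and the column sum equals the total in the header. They also give RPKM, which the authors computed as unique reads per kilobase of transcript length per megaread of the header total. The authors' table of comparisons with HD gives log2 values, which equal the log2 ratio of their group means with a mean of 0 replaced by 0.001. It also gives, per the file headers, an adjusted p-value for each transcript, whose test and adjustment are not given in the sources used here. The aligner, the genome build and the annotation version are not given in the sources used here. The reference table of RefSeq symbols matched none of the files' transcript names, so no coordinates are given.

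Depth was 5.55 to 7.49 megareads (Mreads) of unique reads per library. A transcript absent from a library's file was taken as 0 reads. At least 1 read in at least 1 library was found for 30402 transcripts of 25499 loci, and 8628 of them belong to loci with 2 or more transcripts. A protein database description named 1820 transcripts, a KEGG description 9465 and GO terms alone 8207, while 10910 had no annotation. A floor of 3 reads per library was used where a state had no read, which gives a fold as a lower bound. With 1 to 3 reads in a state the ratio has a 95% counting interval (exact binomial). Bounds and intervals cover counting error only, since reads are not independent molecules. Self-tests on simulated data recovered 90 to 95% of changes of 1.5 on the log2 scale and 97 to 100% of changes of 3, with 1 to 6 false calls per comparison. They held 200 changed transcripts among 16419 to 17941 tested, far fewer than were called in the data. Scaling and false calls with as many changes as in the data were thus not tested by them.

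Counts were tested with the edgeR 4.0.16 quasi-likelihood test (robust) in R 4.3.3, with TMM scaling, filterByExpr by state with a minimum count of 10, and 1 fit of 5 group means to all 15 libraries. The filter left 19108 transcripts. A transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Tests are two-sided. The 4 comparisons with HD and the 3 consecutive comparisons SDH against MDH, PRE against SDH and FRE against PRE were made. FRE against SDH served for the count of reverted changes. Reverted means called in FRE against SDH in the direction opposite to SDH against HD, whatever the level in HD. CPM values use TMM-scaled library totals. RPKM were used for an alternative fit only.

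The 25 gene lists were fixed as text patterns before the data were examined, and 21 had at least 5 tested members. All but the organelle list, which was not searched, were matched to descriptions, and to GO terms where no description exists. Each of the 21 lists was tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 21 lists of a comparison, and again with an estimated correlation. Transcripts named in the text follow a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls against HD, the 4 of each in consecutive comparisons, and up to 2 each way per list. Each must be called, have a mean of at least 5 CPM in a state, an informative description and no overlap between the 3 libraries of both states. The LEA transcripts are both members of their list, and transcripts chosen after their values were seen are named as such. The Fe-Mn superoxide dismutase, ctr family and ferric reductase-like transcripts are given in states outside the rule as well.

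Alternatives fixed before the data were examined were DESeq2 1.42.0, upper quartile scaling, the library total as the only scaling, no filter on low counts, a replicate block, a fit of only the 2 states compared, no minimum fold, an adjusted p of at most 0.001, limma-trend on log2(RPKM + 1), and leaving out each library in turn. Added after the data were seen were replicates 2 and 3 summed, replicates 2 and 3 only, counts summed per locus, list members named by description only, and removal of each library's trend of log2 CPM with transcript length. Replicates 2 and 3 of a state lay closer together than either lay to replicate 1. Their chi-square per degree of freedom over transcripts was 1.25 to 1.56, against 2.90 to 15.6 for pairs with replicate 1, so p-values may in part measure technical spread. Among transcripts with 20 to 100 reads, replicates 2 and 3 lay near counting error in HD (1.02, p = 0.149), SDH (1.02, p = 0.178) and PRE (0.995, p = 0.583), less so in MDH (1.07, p = 0.00021) and FRE (1.13, p = 7.3e-10; chi-square tests). Among transcripts with over 10000 reads the value for replicates 2 and 3 was 4.59 (HD) to 12.5 (FRE), above counting error. For pairs with replicate 1 it was 42.4 to 406 there. Whether replicates 2 and 3 are repeats of 1 biological sample stays open. The libraries were kept as 3 samples, since the design calls them biological. Across states, the departures of replicate 1 libraries from their state means correlated positively in all 10 pairs (0.02 to 0.28). An effect shared by replicate 1 libraries is thus not excluded, and the replicate block is the alternative that allows for it.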

Results

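Transcript levels were measured by RNA sequencing in leafy shoots (gametophores) of the moss Physcomitrium patens as the plants dried and were wetted again. The 15 libraries fell into 5 states of 3 libraries each: hydrated (HD), mildly dehydrated (MDH, called moderate in the series design), severely dehydrated (SDH, called desiccated there), partially rehydrated (PRE) and fully rehydrated (FRE). Depth in megareads (Mreads) of unique reads was 6.67 to 6.85 in HD libraries, 6.76 to 7.11 in MDH, 7.39 to 7.49 in SDH, 6.22 to 7.27 in PRE and 5.55 to 5.80 in FRE. At least 1 read was found for 25150 to 25206 transcripts in HD libraries, 22916 to 23826 in MDH, 22692 to 23238 in SDH, 24920 to 25140 in PRE and 24557 to 24720 in FRE. The 100 most abundant transcripts of a library took 13.0 to 13.5% of the reads in HD, 23.5 to 26.3% in MDH, 28.2 to 29.1% in SDH, 12.4 to 13.5% in PRE and 16.3 to 17.0% in FRE. Levels below are CPM (TMM-scaled counts per Mread), mean ± SD over the 3 libraries of a state. Descriptions are those the deposited files pair with each transcript, from protein database, KEGG or GO matches, so a description may be that of a related protein.

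The first principal component of the 19108 tested transcripts held 59.0% of the variance and set the MDH and SDH libraries apart from the rest. The second held 15.9% and set PRE apart from HD, with FRE between them. The counts of higher and lower transcripts depended on scaling. With the library total as the only scaling, the median log2 fold change of all tested transcripts was -0.56 in MDH against HD, -0.89 in SDH against HD, -0.11 in FRE against HD, -0.32 in SDH against MDH, 0.97 in PRE against SDH and -0.14 in FRE against PRE, and it was 0.00 in PRE against HD. With TMM scaling these medians lay between -0.05 and 0.12, and changes below are relative to that scaling.

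**Figure D1:**
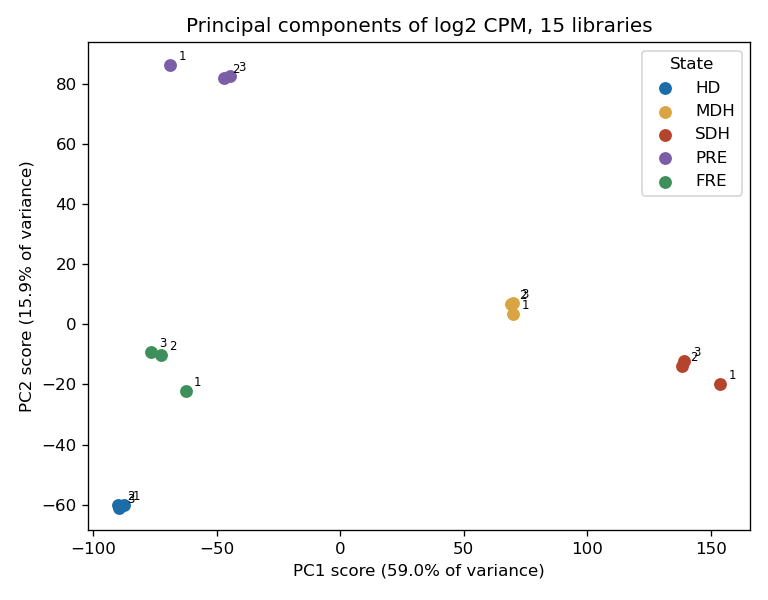
Principal component scores of the 15 libraries from log2 CPM of 19108 transcripts, with the first component (59.0% of the variance) on the horizontal axis, the second (15.9%) on the vertical axis, 1 point per library, colour for the state and the replicate number beside the point. MDH and SDH libraries lie on the right, away from HD, PRE and FRE.

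Mild dehydration was compared with the hydrated state to see which transcripts changed early in drying. Early light-inducible proteins, thylakoid proteins that accumulate under light and water stress, rose from near 0: early light-induced protein 9 (Pp1s25_319V6.1) went from 0.443 ± 0.305 CPM in HD to 600.5 ± 33.3 CPM in MDH (log2 fold change 10.35 ± 1.22 (SE), adjusted p = 1.9e-05, higher in 3 of 3 libraries). A second transcript with that description (Pp1s172_69V6.1) reached 156 ± 20.7 CPM, 1921-fold higher with a counting interval of 531 to 15869, and early light-induced protein 10 (Pp1s15_459V6.1) had no read in HD and 27.3 ± 1.03 CPM in MDH, at least 75.3-fold higher. Of this list 8 higher and 0 lower of 9 tested transcripts were called (camera adjusted p = 3.7e-04, and adjusted p = 0.267 with an estimated correlation). Both transcripts described as group 1 LEA proteins, which are linked to desiccation tolerance, rose too, Pp1s12_68V6.1 from 0.242 ± 0.121 to 23.2 ± 1.3 CPM and Pp1s172_27V6.1 from 0.0804 ± 0.0696 to 6.19 ± 0.488 CPM. With 2 members the LEA list was too small for a list test.

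Antioxidant enzymes rose in MDH, with 50 higher and 17 lower of 134 tested (camera adjusted p = 4.3e-04, and adjusted p = 0.108 with an estimated correlation). With the library total as the only scaling the list had 32 higher and 28 lower. Among the largest rises were a pair of transcripts described as catalase, which breaks down hydrogen peroxide: Pp1s223_74V6.1 from 1.61 ± 0.505 to 1065 ± 349 CPM (log2 fold change 9.35 ± 0.85 (SE)) and Pp1s292_18V6.1 from 24.5 ± 3.59 to 3739 ± 1054 CPM (log2 fold change 7.25 ± 0.69 (SE)). An Fe-Mn superoxide dismutase (Pp1s98_114V6.1) fell from 52.7 ± 2.56 CPM to no read in any of the 3 MDH libraries, at least 103-fold lower. Ribosomal proteins had 105 higher and 32 lower of 512 tested (camera adjusted p = 8.5e-13, and adjusted p = 0.0944 with an estimated correlation), a direction that turned to 13 higher and 58 lower with the library total as the only scaling. A ribosomal protein L10e rose (Pp1s347_24V6.2, log2 fold change 5.20 ± 0.19 (SE)), while another L10e transcript (Pp1s144_140V6.1) fell (log2 fold change -3.30 ± 0.26 (SE)). Other large rises were an alpha-glucosidase (Pp1s13_451V6.1, 0.644 ± 0.348 to 539 ± 156 CPM) and a zeta-carotene desaturase (Pp1s51_28V6.1, 115 ± 3.49 to 17994 ± 3829 CPM).

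Transcripts of the light reactions fell in MDH, with 4 higher and 94 lower of 123 tested (camera adjusted p = 1.1e-19, and adjusted p = 0.0691 with an estimated correlation). A light-harvesting complex II chlorophyll a/b binding protein (Pp1s23_96V6.1) fell from 75 ± 4.42 to 0.281 ± 0.251 CPM (log2 fold change -7.96 ± 0.53 (SE)). A member that rose, Pp1s79_92V6.2 (log2 fold change 1.67 ± 0.12 (SE)), has GO terms for the chloroplast thylakoid and endopeptidase activity and no photosystem description.  Chlorophyll and carotenoid synthesis had 9 higher and 35 lower of 81 tested (camera adjusted p = 0.00307, and adjusted p = 0.11 with an estimated correlation), with a protochlorophyllide reductase (Pp1s108_171V6.1, log2 fold change -4.74 ± 0.46 (SE)). Without MDH replicate 3 the log2 fold changes were -8.60 (Pp1s23_96V6.1, MDH against HD) and -5.38 (Pp1s108_171V6.1, MDH against HD). Calvin cycle enzymes, which fix carbon, had 7 higher and 22 lower of 51 tested (camera adjusted p = 0.0253, and adjusted p = 0.267 with an estimated correlation). A ribulose-bisphosphate carboxylase small chain (Pp1s374_42V6.1) fell from 296 ± 48.1 to 26.9 ± 7.82 CPM, and a transketolase (Pp1s213_103V6.1) rose from 21.9 ± 1.46 to 1105 ± 136 CPM.

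Cell wall, aquaporin, cell cycle and photoreceptor lists also fell in MDH. Cell wall enzymes had 12 higher and 64 lower of 126 tested (camera adjusted p = 5.3e-05, and adjusted p = 0.0944 with an estimated correlation). A pectinesterase (Pp1s236_72V6.1) went from 118 ± 4.54 to 1.2 ± 0.621 CPM. Aquaporins, which are water channels, had 2 higher and 12 lower of 20 tested (camera adjusted p = 0.00481, and adjusted p = 0.167 with an estimated correlation). A plasma membrane aquaporin (Pp1s8_151V6.1) fell from 269 ± 6.86 to 23 ± 0.701 CPM (log2 fold change -3.55 ± 0.10 (SE)), while a tonoplast aquaporin TIP (Pp1s44_31V6.1) rose from 659 ± 55.8 to 2172 ± 710.2 CPM. The list of DNA replication, histones and cell cycle had 8 higher and 78 lower of 216 tested (camera adjusted p = 0.00193, and adjusted p = 0.267 with an estimated correlation), and a kinesin, a microtubule motor, fell strongly (Pp1s54_20V6.1, log2 fold change -4.57 ± 0.46 (SE)). Its log2 fold change (Pp1s54_20V6.1, MDH against HD) was -5.17 without MDH replicate 3. Photoreceptor and clock transcripts had 2 higher and 22 lower of 49 tested (camera adjusted p = 0.00193, and adjusted p = 0.0875 with an estimated correlation), with a phytochrome-interacting factor 3 (Pp1s69_90V6.1) at log2 fold change -4.14 ± 0.34 (SE). Among the largest falls besides the superoxide dismutase, a ctr family transporter (Pp1s54_7V6.1) went from 36.8 ± 2.44 CPM to no read, at least 72.2-fold lower, and ferric reductase-like components Pp1s54_173V6.1 and Pp1s90_3V6.1 fell from 2272 ± 229 to 2.51 ± 0.482 CPM and from 591 ± 9.97 to 0.337 ± 0.157 CPM.

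In all, 7077 of 19108 transcripts differed between MDH and HD (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 2967 higher and 4110 lower. Of these 41.9% were higher, against 18.8% with the library total as the only scaling. Adjusted over the list alone, the list counts differed by at most 1 transcript. With the library total alone the Calvin cycle call ended and the other 9 were kept. None of the 10 list calls passed with an estimated correlation, as the values beside each list show.

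**Figure D2:**
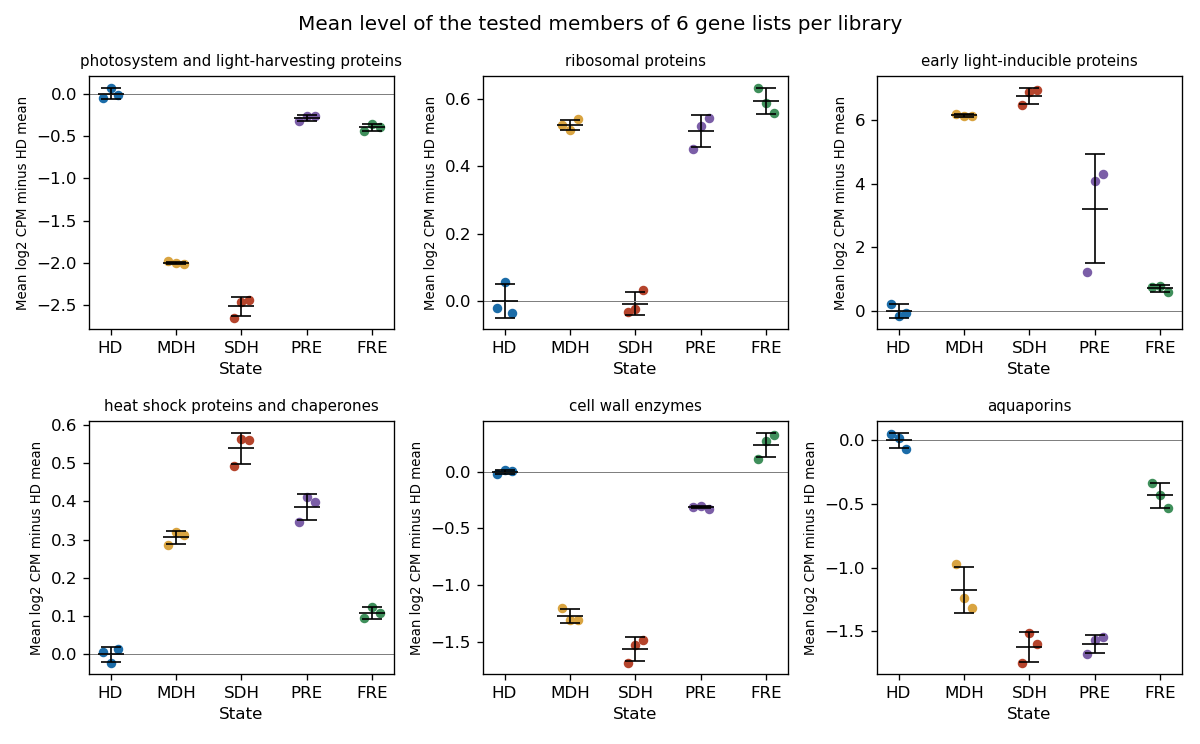
Mean log2 CPM of the tested members of 6 gene lists in each library, minus the HD mean, on the vertical axis against the 5 states on the horizontal axis, with 1 point per library and the mean and SD of each state in black. Photosystem members average -1.98 to -2.01 in the MDH libraries and -2.44 to -2.65 in the SDH libraries; with the library total as the only scaling the ribosomal list in MDH and the heat shock list in SDH turn their majority direction.

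Severe dehydration was compared with the hydrated state to describe the dry tissue. The early light-inducible list had 9 higher and 0 lower of 9 tested (camera adjusted p = 5.4e-04, and adjusted p = 0.326 with an estimated correlation), with Pp1s25_319V6.1 at 765 ± 23.2 CPM and Pp1s15_459V6.1 at 47.4 ± 9.51 CPM against none in HD, at least 131-fold higher. The LEA transcripts stood at 16.1 ± 6.36 CPM (Pp1s12_68V6.1) and 7.87 ± 2.46 CPM (Pp1s172_27V6.1). The catalase Pp1s223_74V6.1 reached 1627 ± 123 CPM (log2 fold change 9.96 ± 0.87 (SE)) and the alpha-glucosidase Pp1s13_451V6.1 697 ± 24.3 CPM (log2 fold change 10.04 ± 0.74 (SE)). A CASP-like membrane protein (Pp1s87_107V6.2) rose from 2.01 ± 0.692 to 1822 ± 82.2 CPM. The zeta-carotene desaturase Pp1s51_28V6.1 stood at 24294 ± 1578 CPM.

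Heat shock proteins and chaperones, which assist protein folding, had 56 higher and 28 lower of 152 tested (camera adjusted p = 0.00644, and adjusted p = 0.0129 with an estimated correlation), a direction that turned to 35 higher and 47 lower with the library total as the only scaling. A heat shock 70kDa protein 1/8 (Pp1s298_26V6.1) rose from 42.3 ± 5.9 to 1569 ± 74.5 CPM (log2 fold change 5.21 ± 0.15 (SE)), and a chaperone DnaJ (Pp1s100_218V6.1) fell from 12.2 ± 1.28 to 0.387 ± 0.335 CPM. Proteasome and ubiquitin ligase transcripts had 101 higher and 70 lower of 352 tested (camera adjusted p = 0.0222, and adjusted p = 0.208 with an estimated correlation), which turned to 22 higher and 122 lower with the library total alone and to 69 higher and 91 lower with upper quartile scaling. Members moved strongly both ways, such as the HERC4-type ubiquitin ligases Pp1s196_82V6.1 (log2 fold change 4.80 ± 0.36 (SE)) and Pp1s125_31V6.1 (216-fold lower with a counting interval of 38.5 to 8544).

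Light-reaction transcripts were lower in SDH, with 4 higher and 100 lower of 123 tested (camera adjusted p = 3.1e-18, and adjusted p = 0.044 with an estimated correlation). A light-harvesting complex I protein (Pp1s161_32V6.2) fell from 25 ± 3.83 to 0.199 ± 0.202 CPM, 128-fold lower with a counting interval of 43.5 to 620.3, while another (Pp1s213_80V6.1) rose from 1793 ± 6.5 to 4694 ± 84.2 CPM (log2 fold change 1.39 ± 0.14 (SE)), a call lost with the library total as the only scaling. Calvin cycle enzymes had 7 higher and 27 lower of 51 tested (camera adjusted p = 0.00644, and adjusted p = 0.208 with an estimated correlation). Phosphoribulokinase (Pp1s20_273V6.1) fell from 259 ± 12 to 7.63 ± 2.29 CPM. Chlorophyll and carotenoid synthesis had 12 higher and 43 lower of 81 tested (camera adjusted p = 0.0058, and adjusted p = 0.136 with an estimated correlation), and photoreceptors 1 higher and 27 lower of 49 tested (camera adjusted p = 8.6e-04, and adjusted p = 0.0524 with an estimated correlation). Nitrogen metabolism had 5 higher and 20 lower of 45 tested (camera adjusted p = 0.00708, and adjusted p = 0.0954 with an estimated correlation): a nitrate reductase (Pp1s79_76V6.2) fell from 28 ± 5.02 to 0.263 ± 0.121 CPM and a glutamine synthetase (Pp1s345_10V6.1) from 129 ± 4.88 to 3.65 ± 0.372 CPM. Cell wall enzymes had 15 higher and 73 lower of 126 tested (camera adjusted p = 1.7e-04, and adjusted p = 0.112 with an estimated correlation). Expansin 4 (Pp1s25_294V6.1) went from 11.4 ± 2.63 CPM to no read, at least 19.4-fold lower. Aquaporins had 2 higher and 13 lower of 20 tested (camera adjusted p = 0.00931, and adjusted p = 0.208 with an estimated correlation). Pp1s8_151V6.1 stood at 5.93 ± 1.09 CPM.

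Altogether 9231 transcripts differed between SDH and HD, 3956 higher and 5275 lower. Of these 42.9% were higher, against 17.5% with the library total alone. The list counts differed by at most 1 transcript when adjusted over the list alone. With the library total alone the calls of the Calvin cycle, aquaporin, chlorophyll and proteasome lists ended, 6 of 10 were kept, and antioxidant enzymes and ribosomal proteins were called as well. Of the 10 list calls those for photosystem proteins and for heat shock proteins passed with an estimated correlation.

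SDH was also set against MDH to separate the later part of drying. Ribosomal proteins were lower in SDH, with 3 higher and 59 lower of 512 tested (camera adjusted p = 4.1e-15, and adjusted p = 0.131 with an estimated correlation), and 8 higher and 31 lower with each library's trend with transcript length removed (camera adjusted p = 8.5e-10). Those lower include ribosomal proteins L5 (Pp1s358_49V6.1, log2 fold change -2.22 ± 0.15 (SE)) and L4 (Pp1s134_66V6.1, log2 fold change -2.09 ± 0.14 (SE)). Phenylpropanoid and flavonoid enzymes, which make phenolic compounds, had 7 higher and 38 lower of 110 tested (camera adjusted p = 1.8e-04, and adjusted p = 0.203 with an estimated correlation). A cinnamoyl-CoA reductase (Pp1s75_227V6.1) fell from 189.7 ± 27.2 to 9.73 ± 0.228 CPM. Photosystem transcripts fell further, with 3 higher and 31 lower of 123 tested (camera adjusted p = 8.2e-06, and adjusted p = 0.378 with an estimated correlation). Heat shock proteins had 36 higher and 15 lower of 152 tested (camera adjusted p = 0.0353, and adjusted p = 0.0337 with an estimated correlation), which turned to 15 higher and 17 lower with the library total alone, and an HSP20 family protein (Pp1s148_10V6.1) rose from 0.574 ± 0.292 to 7.23 ± 1.38 CPM. The DNA replication list had 39 higher and 11 lower of 216 tested (camera adjusted p = 0.0376, and adjusted p = 0.551 with an estimated correlation), which turned to 20 higher and 26 lower with the library total alone, with a minichromosome maintenance protein 8 (Pp1s16_310V6.1) from 8.21 ± 1.32 to 51.1 ± 6.73 CPM. The call of the DNA replication list ended with the length trend removed (camera adjusted p = 0.0940). An EREBP-like factor (Pp1s98_22V6.1) fell from 31.6 ± 8.09 to 0.134 ± 0.233 CPM, 240.0-fold lower with a counting interval of 66.1 to 1987. In total 4884 transcripts differed, 2291 higher and 2593 lower, and 46.9% of them were higher, against 23.8% with the library total alone and 32.2% with upper quartile scaling. Adjusted over the list alone, the list counts differed by at most 2 transcripts, and only the heat shock call passed with an estimated correlation. The calls of the heat shock and DNA replication lists ended without MDH replicate 1, without MDH replicate 3 or without SDH replicate 3, and with replicates 2 and 3 summed, an alternative chosen after the data were seen. The DNA replication call also ended without SDH replicate 2.

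Partial rehydration was compared with both SDH and HD. Against SDH the light reactions rose: photosystem transcripts had 99 higher and 4 lower of 123 tested (camera adjusted p = 2.0e-16, and adjusted p = 0.121 with an estimated correlation). A photosystem II PsbW protein (Pp1s185_111V6.1) rose from 1.89 ± 0.57 CPM in SDH (log2 fold change 5.19 ± 0.17 (SE)). Calvin cycle enzymes had 26 higher and 7 lower of 51 tested (camera adjusted p = 0.00646, and adjusted p = 0.25 with an estimated correlation). Phosphoribulokinase (Pp1s20_273V6.1) stood at 169 ± 3.34 CPM. Chlorophyll and carotenoid synthesis had 41 higher and 12 lower of 81 tested (camera adjusted p = 0.0111, and adjusted p = 0.238 with an estimated correlation). A magnesium-protoporphyrin O-methyltransferase (Pp1s372_25V6.1) went from 8.65 ± 2.8 to 189 ± 5.43 CPM. Cell wall enzymes had 75 higher and 20 lower of 126 tested (camera adjusted p = 7.9e-04, and adjusted p = 0.201 with an estimated correlation). Among them beta-expansin 1 (Pp1s251_59V6.1), a wall-loosening protein, had no read in SDH and 13.9 ± 0.695 CPM in PRE, at least 23.6-fold higher, and expansin 3 (Pp1s246_53V6.1) rose from 0.527 ± 0.242 to 60.1 ± 2.95 CPM. Ribosomal proteins had 118 higher and 18 lower of 512 tested (camera adjusted p = 0.0042, and adjusted p = 0.444 with an estimated correlation), and their call ended with the length trend removed (camera adjusted p = 0.222).

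All 9 tested early light-inducible transcripts fell from SDH to PRE (camera adjusted p = 0.00646, and adjusted p = 0.444 with an estimated correlation), such as early light-induced protein 12 (Pp1s196_69V6.1) from 10889 ± 282 to 854 ± 513 CPM. The PRE libraries differed here: the list averaged 1.23 log2 units above HD in PRE replicate 1 and 4.09 and 4.30 in replicates 2 and 3. Proteasome and ubiquitin ligase transcripts had 53 higher and 108 lower of 352 tested (camera adjusted p = 0.0042, and adjusted p = 0.201 with an estimated correlation), which turned to 112 higher and 42 lower with the library total alone. In total 9501 transcripts differed between PRE and SDH, 5224 higher and 4277 lower; 55.0% were higher, against 82.1% with the library total alone. The list counts differed by 0 transcripts when adjusted over the list alone. With the library total alone the calls of the cell wall, chlorophyll and proteasome lists ended, 4 of 7 were kept, and abscisic acid signalling was called as well. None of the 7 list calls passed with an estimated correlation.

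Against HD, PRE differed in several lists. Ribosomal proteins were higher, with 99 higher and 8 lower of 512 tested (camera adjusted p = 1.1e-09, and adjusted p = 0.126 with an estimated correlation). A ribosomal protein L20 (Pp1s152_64V6.1) stood at 34.8 ± 0.534 against 4.1 ± 1.35 CPM. Heat shock proteins had 46 higher and 20 lower of 152 tested (camera adjusted p = 0.00466, and adjusted p = 0.00899 with an estimated correlation), with an HSP20 family protein up from 1.65 ± 0.259 CPM in HD (Pp1s77_290V6.1, log2 fold change 6.09 ± 0.37 (SE)). A chaperone DnaJ (Pp1s354_16V6.1) fell from 17.4 ± 2.3 to 0.443 ± 0.209 CPM. Antioxidant enzymes had 34 higher and 10 lower of 134 tested (camera adjusted p = 0.00964, and adjusted p = 0.226 with an estimated correlation). A glutathione S-transferase (Pp1s271_8V6.1) rose from 12.2 ± 1.07 to 457 ± 223 CPM. Early light-inducible transcripts had 8 higher and 1 lower of 9 tested (camera adjusted p = 0.0139, and adjusted p = 0.431 with an estimated correlation). Aquaporins had 0 higher and 13 lower of 20 tested (camera adjusted p = 5.8e-05, and adjusted p = 0.0665 with an estimated correlation). Pp1s8_151V6.1 stood at 17.1 ± 0.735 CPM (log2 fold change -3.97 ± 0.10 (SE)). Nitrogen metabolism had 4 higher and 16 lower of 45 tested (camera adjusted p = 0.00831, and adjusted p = 0.0717 with an estimated correlation). A ferredoxin-nitrite reductase (Pp1s214_53V6.1) fell from 10.6 ± 1.06 to 0.0876 ± 0.152 CPM, 134-fold lower with a counting interval of 36.8 to 1113.

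Abscisic acid signalling, the hormone pathway of water stress, had 2 higher and 14 lower of 38 tested in PRE against HD (camera adjusted p = 0.0042, and adjusted p = 0.0665 with an estimated correlation). An ABA responsive element binding factor (Pp1s49_161V6.1) fell from 17.3 ± 1.69 to 4.41 ± 1.43 CPM. Autophagy proteins had 0 higher and 8 lower of 12 tested (camera adjusted p = 0.0146, and adjusted p = 0.226 with an estimated correlation). Photoreceptors had 2 higher and 23 lower of 49 tested (camera adjusted p = 0.00109, and adjusted p = 0.0665 with an estimated correlation). A phototropin (Pp1s59_175V6.1) fell from 36.8 ± 2.95 to 5.17 ± 0.738 CPM. Photosystem transcripts had 3 higher and 16 lower of 123 tested (camera adjusted p = 0.0139, and adjusted p = 0.431 with an estimated correlation), and phenylpropanoid enzymes 12 higher and 27 lower of 110 tested (camera adjusted p = 0.0498, and adjusted p = 0.363 with an estimated correlation). The phenylpropanoid call ended with the length trend removed (camera adjusted p = 0.0659), with the replicate block, and without HD replicate 2, HD replicate 3 or PRE replicate 1. In total 5696 transcripts differed between PRE and HD, 2663 higher and 3033 lower. Adjusted over the list alone, the list counts differed by at most 1 transcript, and of the 11 list calls only that for heat shock proteins passed with an estimated correlation.

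Full rehydration was compared with PRE and with HD. From PRE to FRE water channels rose, with 11 higher and 0 lower of 20 tested aquaporins (camera adjusted p = 3.3e-04, and adjusted p = 0.0712 with an estimated correlation). Pp1s8_151V6.1 rose from 17.1 ± 0.735 to 115 ± 8.85 CPM. Autophagy proteins had 8 higher and 0 lower of 12 tested (camera adjusted p = 4.3e-04, and adjusted p = 0.0712 with an estimated correlation), phenylpropanoid enzymes 36 higher and 4 lower of 110 tested (camera adjusted p = 7.7e-05, and adjusted p = 0.0712 with an estimated correlation) and nitrogen metabolism 17 higher and 3 lower of 45 tested (camera adjusted p = 0.00682, and adjusted p = 0.0712 with an estimated correlation). A phenylalanine ammonia-lyase (Pp1s43_67V6.1), the entry enzyme of phenylpropanoid synthesis, rose from 8.6 ± 1.54 to 56 ± 9.5 CPM, and a nitrate transporter (Pp1s75_75V6.1) from 5.33 ± 1.64 to 142 ± 25.9 CPM. Cell wall enzymes had 35 higher and 10 lower of 126 tested (camera adjusted p = 0.00592, and adjusted p = 0.219 with an estimated correlation), and abscisic acid signalling 8 higher and 1 lower of 38 tested (camera adjusted p = 0.00682, and adjusted p = 0.0712 with an estimated correlation).

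Heat shock proteins fell from PRE to FRE, with 23 higher and 38 lower of 152 tested (camera adjusted p = 0.00829, and adjusted p = 0.0186 with an estimated correlation). The HSP20 family protein Pp1s77_290V6.1 fell to 1.36 ± 0.489 CPM in FRE (log2 fold change -6.36 ± 0.40 (SE)), while another (Pp1s350_28V6.1) rose from 187 ± 6.51 to 2228 ± 388 CPM. Early light-inducible transcripts had 1 higher and 8 lower of 9 tested (camera adjusted p = 0.0329, and adjusted p = 0.507 with an estimated correlation). The DNA replication list had 14 higher and 43 lower of 216 tested (camera adjusted p = 8.1e-05, and adjusted p = 0.207 with an estimated correlation), with kinesin Pp1s242_11V6.1 down from 53.9 ± 4.23 to 10.7 ± 3.93 CPM, and chlorophyll and carotenoid synthesis had 7 higher and 18 lower of 81 tested (camera adjusted p = 0.0434, and adjusted p = 0.247 with an estimated correlation). In total 4431 transcripts differed between FRE and PRE, 2522 higher and 1909 lower; 56.9% were higher, against 43.8% with the library total alone. The calls of the early light-inducible and chlorophyll lists ended with the library total alone, without PRE replicate 2, without PRE replicate 3, without FRE replicate 3, and with replicates 2 and 3 summed; the chlorophyll call also ended without PRE replicate 1 or FRE replicate 1. The list counts differed by at most 1 transcript when adjusted over the list alone, and of the 10 list calls only that for heat shock proteins passed with an estimated correlation.

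FRE was compared with HD to see which changes were still present after rewetting. Ribosomal proteins were higher, with 77 higher and 1 lower of 512 tested (camera adjusted p = 1.6e-24, and adjusted p = 0.0636 with an estimated correlation) and a median log2 fold change of 0.71. These are short transcripts, with a median length of 882.5 bases, and length went with change in this comparison: the Spearman correlation of length with log2 fold change across the 19108 transcripts, which are not independent replicates, was -0.29, and the median log2 fold change was 0.29 among the shortest transcripts (median length 795 bases) and -0.27 among the longest (median length 2979 bases). With each library's length trend removed, 12 ribosomal transcripts were called higher and 1 lower, and the list kept its call (camera adjusted p = 1.4e-13). Antioxidant enzymes had 33 higher and 4 lower of 134 tested (camera adjusted p = 5.2e-04, and adjusted p = 0.214 with an estimated correlation), and 26 higher and 3 lower with the length trend removed. A glutathione S-transferase (Pp1s66_172V6.1), which conjugates glutathione to reactive compounds, rose from 11.9 ± 3.06 to 936 ± 154 CPM (log2 fold change 6.29 ± 0.29 (SE), adjusted p = 1.6e-09, higher in 3 of 3 libraries). Phenylpropanoid enzymes had 29 higher and 8 lower of 110 tested (camera adjusted p = 0.0483, and adjusted p = 0.395 with an estimated correlation). A phenylalanine ammonia-lyase (Pp1s494_3V6.1) rose from 2.09 ± 0.293 to 22.7 ± 1.52 CPM.

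The DNA replication list, with a median length of 2370.5 bases, had 1 higher and 42 lower of 216 tested in FRE against HD (camera adjusted p = 5.0e-05, and adjusted p = 0.286 with an estimated correlation), and 1 higher and 22 lower with the length trend removed; kinesin Pp1s54_20V6.1 fell from 25.9 ± 3.81 to 6.23 ± 3.7 CPM. Photosystem transcripts had 1 higher and 14 lower of 123 tested (camera adjusted p = 3.2e-07, and adjusted p = 0.25 with an estimated correlation), and 1 higher and 22 lower with the length trend removed. The light-harvesting complex I protein Pp1s213_80V6.1 fell from 1793 ± 6.5 to 593 ± 11.8 CPM. Photoreceptors had 2 higher and 12 lower of 49 tested (camera adjusted p = 0.0011, and adjusted p = 0.094 with an estimated correlation). Phototropin B1 (Pp1s84_194V6.1) fell from 705 ± 42.5 to 175 ± 21 CPM, and chlorophyll and carotenoid synthesis had 7 higher and 16 lower of 81 tested (camera adjusted p = 0.0483, and adjusted p = 0.36 with an estimated correlation). The Fe-Mn superoxide dismutase Pp1s98_114V6.1 stood at 0.0544 ± 0.0941 CPM (1000-fold lower with a counting interval of 179 to 39546), the ctr family transporter Pp1s54_7V6.1 at 0.104 ± 0.0899 CPM (349-fold lower with a counting interval of 96.4 to 2888) and the ferric reductase-like Pp1s90_3V6.1 at 1.04 ± 0.482 CPM, while Pp1s54_173V6.1 was at 393 ± 85.6 CPM after 16.5 ± 11.5 CPM in SDH. An EREBP-like factor (Pp1s117_23V6.1) fell from 40.6 ± 1.77 to 0.954 ± 0.336 CPM. In total 2841 transcripts differed between FRE and HD, 1396 higher and 1445 lower; 49.1% were higher, against 36.1% with the library total alone and 56.1% with upper quartile scaling, so which direction has more depends on scaling. Adjusted over the list alone, the list counts differed by at most 2 transcripts, and none of the 7 list calls passed with an estimated correlation. The phenylpropanoid and chlorophyll calls both ended with the replicate block, without HD replicate 1, without HD replicate 2, and with replicates 2 and 3 summed. The phenylpropanoid call also ended without FRE replicate 2 or FRE replicate 3, and the chlorophyll call without FRE replicate 1 or with the library total alone.

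**Figure D3:**
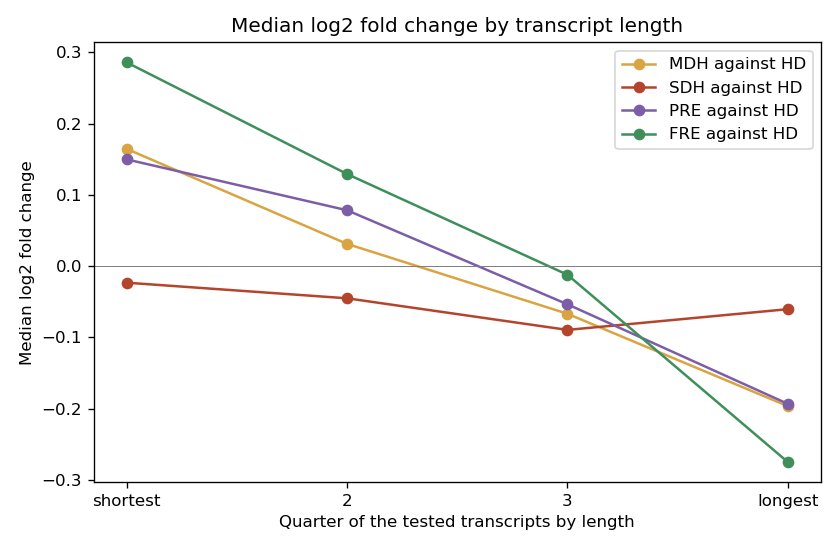
Median log2 fold change against HD (vertical axis) of the tested transcripts in 4 groups of equal size by transcript length (horizontal axis, shortest to longest), 1 line per state. In FRE it runs from 0.29 in the shortest group to -0.27 in the longest, in MDH from 0.16 to -0.20, in PRE from 0.15 to -0.19 and in SDH from -0.02 to -0.06.

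**Figure D4:**
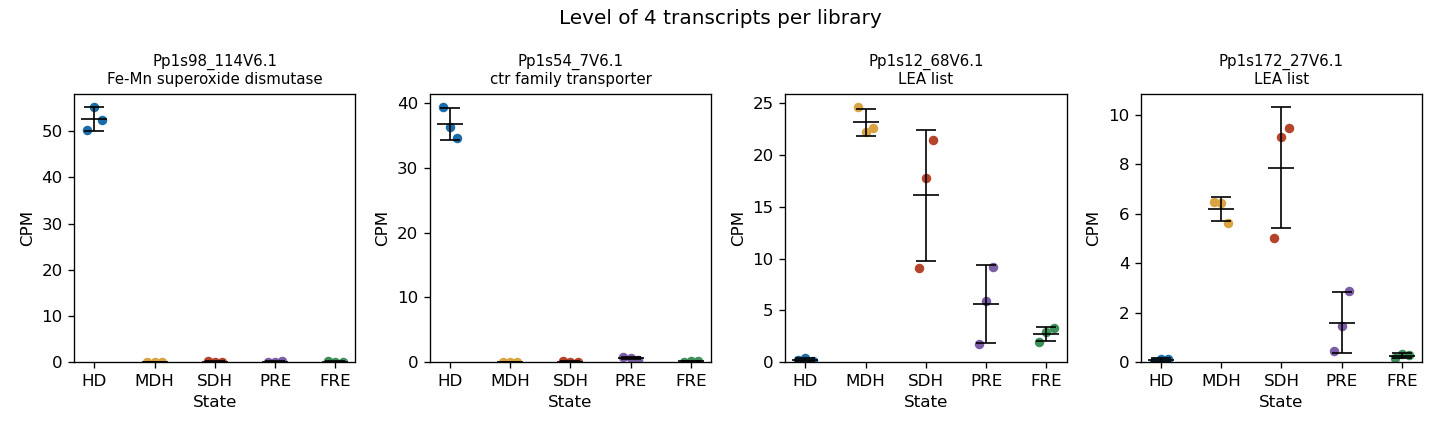
CPM (vertical axis, from 0) of 4 transcripts in the 5 states (horizontal axis), 1 point per library with the mean and SD of each state in black. The Fe-Mn superoxide dismutase and the ctr family transporter are at 52.7 and 36.8 CPM in HD and below 1 CPM in every other state, and the LEA transcripts are highest in MDH and SDH.

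Overlap between states was counted last. MDH and SDH shared 5451 calls in the same direction, 2138 higher and 3313 lower, where independent lists of these sizes would share 614 and 1135. SDH and PRE shared 2709, 1012 higher and 1697 lower, where independent lists would share 551 and 837. In 20 draws with all libraries, those of HD included, simulated from the HD means, 0 calls were shared. These draws hold no true change, so they cannot show how far shared controls raise the overlap of real changes. The 3 HD libraries are too few to divide, so part of each excess may come from the shared controls. Of the 3956 transcripts higher in SDH than in HD, 2961 (74.8%) were lower in FRE than in SDH and 578 (14.6%) were still called higher in FRE than in HD. Of the 5275 lower in SDH, 4263 (80.8%) were higher in FRE than in SDH and 839 (15.9%) were still called lower in FRE than in HD. The SDH libraries enter both the selection and the comparison with FRE, which favours reversal. In 10 simulated draws 0 transcripts reverted where FRE was given the SDH means, and in 10 others 0 were still called where FRE was given the HD means. In PRE, 2813 (71.1%) and 3744 (71.0%) were called against SDH in the opposite direction. In the same direction against HD, 1012 (25.6%) and 1697 (32.2%) were still called, and no such draws were made for PRE. An opposite call against SDH sets no condition on the HD level. It thus includes partial returns and levels beyond HD, and a transcript can be in both counts. Between SDH and PRE, 620 transcripts were called on opposite sides of HD.

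The lists of AP2/ERF factors, of sucrose, trehalose and raffinose metabolism, of tubulins and actins, of lipoxygenases and lipases and of sperm axoneme proteins, a marker of antheridia, were not called in any of the 7 comparisons. The AP2/ERF patterns do not match the description EREBP-like factor. The EREBP-like factors named in this text, which changed strongly, thus lie outside that list and its test. Of the 17 tested axoneme transcripts 2 were higher and 6 lower in MDH than in HD. The rhizoid list matched 0 transcripts, and the sporophyte homeobox list matched 5, of which 0 were tested. The organelle list was not searched, since no gene symbols or organelle sequence names are given, so organelle transcripts were not assessed. By the same thresholds the authors' deposited comparisons gave 8075 changed transcripts in MDH, 10445 in SDH, 6766 in PRE and 3884 in FRE, each against HD. Of the calls made here 6692, 8651, 5591 and 2749 had a call in the same direction there and 0 in the opposite one.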

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

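The examples in this part were chosen after their values were seen. Some transcripts were called in opposite directions in 2 states against HD (edgeR quasi-likelihood test, Benjamini-Hochberg). Between MDH and SDH there were 79, of which 69 were higher in MDH and lower in SDH and 10 the reverse. EREBP-like factor Pp1s11_280V6.1, of a family of plant transcription factors, stood at 5.31 ± 0.600 CPM in HD, 51.0 ± 16.7 CPM in MDH and 1.17 ± 0.175 CPM in SDH. Hydroperoxide dehydratase Pp1s97_112V6.1, an enzyme of oxylipin synthesis, stood at 474 ± 5.16, 1236 ± 276 and 72.8 ± 4.64 CPM in these states.

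Between SDH and PRE there were 620 such transcripts, 266 higher and then lower and 354 lower and then higher. ABA responsive element binding factor Pp1s49_161V6.1 stood at 17.3 ± 1.69 CPM in HD, 81.0 ± 2.96 CPM in SDH and 4.41 ± 1.43 CPM in PRE. Expansin 3 Pp1s246_53V6.1 stood at 4.11 ± 0.570 CPM in HD, 0.527 ± 0.242 CPM in SDH and 60.1 ± 2.95 CPM in PRE.

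Between PRE and FRE there were 84, 14 higher and then lower and 70 lower and then higher. Pectinesterase Pp1s149_288V6.1 stood at 5.52 ± 0.474 CPM in HD, 1.49 ± 0.421 CPM in PRE and 28.2 ± 1.51 CPM in FRE. Phenylalanine ammonia-lyase Pp1s43_67V6.1 stood at 19.3 ± 2.14 CPM in HD, 8.60 ± 1.54 CPM in PRE and 56.0 ± 9.50 CPM in FRE.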

How the results depend on the processing

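The counts of changed transcripts stayed within 1.5 times the reported ones under every alternative run except no minimum fold, by whose construction more transcripts pass: 13030 in MDH against HD, 14146 in SDH against HD, 12153 in PRE against HD, 9101 in FRE against HD, 10873 in SDH against MDH, 14391 in PRE against SDH and 10890 in FRE against PRE. It gave 9958 and 6435 shared calls (MDH and SDH, SDH and PRE) and 11313 reverted changes. With an estimated correlation 0, 2, 1, 0, 1, 0 and 1 lists were called in the same order of comparisons, against 10, 10, 11, 7, 5, 7 and 10, and the cause was not tested. With replicates 2 and 3 summed, an alternative chosen after the data were seen, 3 lists were called in SDH against MDH, the calls of the DNA replication and heat shock lists being the ones lost, and the cause was not tested. Leaving out 1 library at a time gave 7048 to 7228, 9039 to 9430, 5662 to 5778, 2608 to 3072, 4540 to 5021, 9298 to 9634 and 4074 to 4698 changed transcripts, and 10 to 11, 10 to 11, 10 to 11, 5 to 8, 3 to 5, 7 to 9 and 8 to 10 lists. The lowest value for lists in SDH against MDH came without MDH replicate 1, MDH replicate 3 or SDH replicate 3, where the DNA replication and heat shock calls were lost; the former was lost without SDH replicate 2 too. Shared calls ranged from 5422 to 5615 and from 2663 to 2855, and reverted changes from 6944 to 7343. DESeq2 gave 7475, 9876, 5882, 2795, 4882, 10034 and 4446 changed transcripts and the replicate block 7106, 9247, 5716, 2850, 4880, 9518 and 4445. With that block 5 of the 7 lists were called in FRE against HD, those of chlorophyll synthesis and phenylpropanoids being lost, and 10 of the 11 in PRE against HD, without the phenylpropanoids; the other comparisons kept their lists. No named transcript reversed its direction under an alternative run. Calls of named transcripts were lost most often with limma-trend on log2(RPKM + 1) (57), the library total as the only scaling (31) and the length trend removed (14). The alternative of another pseudocount was not run, since counts were given. Transcripts near 0 reads allow only bounds at this depth.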

Other observations

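Of the tests in this part, those of GO terms, of library scaling, of reads shared with paralogs, of length in MDH, of splits for the counts of changed transcripts and of replicate 1 were chosen after the results were seen. GO terms give groups beyond the fixed lists (387 terms tested with camera). Each term given here had a camera adjusted p of at most 2.7e-05 with the preset correlation. In PRE against HD, mitochondrial respiratory chain transcripts had 27 higher and 0 lower of 63 tested (adjusted p = 0.079 with an estimated correlation). Nuclear lumen transcripts had 75 higher and 8 lower of 240 (adjusted p = 0.0078 with an estimated correlation), and protein transmembrane transporters, which move proteins into organelles, 16 higher and 0 lower of 31 (adjusted p = 0.0078 with an estimated correlation). RNA modification had 14 higher and 0 lower of 29 (adjusted p = 0.036 with an estimated correlation) and translation 49 higher and 6 lower of 187 (adjusted p = 0.036 with an estimated correlation). Aminoacylation of tRNA, which loads amino acids for translation, had 21 higher and 0 lower of 57 in PRE against HD (adjusted p = 0.19 with an estimated correlation) and 0 higher and 25 lower in FRE against PRE (adjusted p = 0.16 with an estimated correlation). In FRE against HD, fatty acid catabolic process had 8 higher and 0 lower of 28 (adjusted p = 0.065 with an estimated correlation), and motor activity 3 higher and 16 lower of 62 (adjusted p = 0.27 with an estimated correlation). With the length trend of FRE against HD removed these were 9 higher and 0 lower (camera adjusted p = 6.0e-06) and 2 higher and 9 lower (camera adjusted p = 0.0020), motor transcripts being long (median length 3480.5 bases).

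The Fe-Mn superoxide dismutase Pp1s98_114V6.1, the ctr family transporter Pp1s54_7V6.1 and the ferric reductase-like Pp1s90_3V6.1 were below 4 CPM in each state other than HD, and ferric reductase-like Pp1s54_173V6.1 was lower than in HD in each but at 439 CPM in PRE and 393 CPM in FRE. Library scaling is argued against by the size of the falls. With the library total alone the lowest median log2 fold change of all tested transcripts against HD was -0.89 (SDH). The smallest of these falls was -2.37 (Pp1s54_173V6.1, PRE). Given these sizes, the 16 of 16 pairs of transcript and state still called lower with the library total alone were fixed in advance. Paralogs of the transporter and the reductases gained at least 50% of the CPM lost in 0 of 12 pairs. For the superoxide dismutase the other 4 transcripts of that description gained that much in 4 of 4 states, from 107 CPM in HD to 167 to 245 CPM. This test cannot decide on shared reads, since the counts are headed as unique reads and the handling of shared reads is not given. Shared reads thus stay open for all 4 transcripts. The first form of this test, set before, counted 4 of 16 pairs, which met its bound against shared reads, and it was divided by transcript because all 4 came from the superoxide dismutase. A response to copper supply is a hypothesis that also stays open. The 4 tested Cu/Zn superoxide dismutases had a median log2 fold change of 1.60 in FRE (3 called higher) and 1.45 in MDH. It was 0.44 in SDH and 0.80 in PRE (1 called higher in each). The prediction of this hypothesis, set before, named FRE alone and asked for a median of at least 1, which was met. That all 4 states reach it was not part of the prediction. SDH and PRE did not reach it, so the hypothesis was left undecided. Other copper-related transcripts, chosen after their values were seen, moved both ways. Against HD the ctr family copper transporter Pp1s130_87V6.1 was called lower in SDH, PRE and FRE. Copper chaperone Pp1s441_13V6.3 was called higher in MDH, SDH and PRE, and copper chaperone Pp1s19_254V6.1 in no state. The plastocyanins were called lower in MDH and SDH. The difference in hydration itself is open too.

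Fewer transcripts had reads in MDH and SDH, and the 100 most abundant took more of the reads there. Sequencing depth is argued against for SDH, whose libraries were deeper than those of HD (7.39 to 7.49 against 6.67 to 6.85 Mreads). Thinning to 1 common total thus could not close that gap. HD libraries then had 2419.7 more transcripts with reads than SDH libraries on average (SD 19.1 in HD and 312 in SDH). For MDH depth is argued against by 22393 to 23243 transcripts at that total, against 24690 to 24726 in HD. Degradation that takes long transcripts first is argued against by a Spearman correlation of length with log2 fold change of -0.0077 across transcripts in SDH against HD, but stays open for MDH, where it was -0.1037, between the bounds of -0.2 and -0.1. A few abundant transcripts taking the reads may account for part: without the top 100 of each library, 81% of the gap was left. That share lay above the bound set before against this explanation. SDH libraries then had 22151 to 22807 transcripts with reads, against 24525 to 24565 in HD. These values argue against the top 100 as the whole cause. The SD of 15.5 over the SDH libraries sets each against 1 mean gap, so it is not the spread of the share. The difference in state itself stays open.

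In FRE against HD shorter transcripts were higher and longer ones lower. The listed genes alone do not carry the trend, since the correlation was -0.2647 across the 16850 transcripts in none of the lists. The trend is argued against as the whole cause of the list calls, since 7 of 7 were kept after its removal, although ribosomal transcripts called higher went from 77 to 12. The trend was not confined to FRE: against HD the correlation was -0.11 in PRE and -0.10 in MDH. Per library the correlation of length with log2 CPM deviation was 0.11 to 0.15 in HD and -0.25 to -0.13 in FRE. It was -0.06 to -0.04 in MDH, 0.06 to 0.08 in SDH and -0.04 to 0.00 in PRE. A bias from RNA or library preparation and a change in the plants could each give such a trend, and the design confounds them with the state.

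With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the only one of the 10 (1 of 10) with as many changed transcripts in each of the 7 comparisons: 7077, 9231, 5696, 2841, 4884, 9501 and 4431, against a highest other of 1 in SDH against MDH and 0 in the rest. For gene lists, 4 of 10 splits gave as many calls in MDH against HD (10, highest other 10), 2 in SDH against HD (10, highest other 10), 1 in PRE against HD (11, highest other 8), 2 in FRE against HD (7, highest other 7), 4 in SDH against MDH (5, highest other 6), 5 in PRE against SDH (7, highest other 8) and 1 in FRE against PRE (10, highest other 6). Other splits thus called as many lists in 5 of the 7 comparisons. Every other split still has 2 libraries of a state on 1 side and 1 on the other, so it keeps part of the state difference.

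Replicate 1 was farthest in depth from the other libraries of its state in 1 of 5 states. Of the 10 correlations between states of how replicate 1 departed from its state mean, 5 were below 0.1 (0.02 to 0.28, median 0.15). Both were chosen after the results were seen, so they are given as values only and decide nothing on depth or on a shared effect.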
